A study of Arabidopsis thaliana with 9 samples.

How the data were processed

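The data are 1-colour Affymetrix ATH1 arrays of RNA from hand-dissected root tips, with about 200 tips per replicate and 250 ng of total RNA labelled with biotin per array, per the labels' protocols. Seedlings grew on vertical plates at 22 °C with 18 h of light and 6 h of dark. The deposited table holds 1 log2 value per probe set and array; per the submitters' processing notes the tools were Affymetrix Expression Console, RMA and limma, whose versions are not given in the sources used here. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set. Such normalization removes global differences in RNA amount, so changes are relative to the other transcripts. Over the 9 arrays the lowest values lay between 2.45 and 2.59 and the array medians between 5.79 and 5.95. No scanner files were used here.

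Arrays were grouped by genotype and numbered 1 to 3 by their titles. The labels call them biological replicates and do not say how seedlings or plates were divided between them. All 22810 probe sets of the table were read, and 64 Affymetrix controls were kept out of the tests, leaving 22746. In the platform annotation used here 13513 probe sets have 1 gene, 503 have several and 8730 are not listed. The 8730 are unnamed here, not without a gene. Symbols were updated through the Entrez identifier with the RefSeq annotation of TAIR10.1, and 77 of the 1-gene probe sets found no match there. No coordinates are printed, because no build is named for the array. No probe set that matches several genes was named.

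Each comparison was fitted with limma 3.58.1 in R 4.3.3, with a mean per genotype over all 9 arrays (6 residual degrees of freedom), empirical Bayes moderation and Benjamini-Hochberg adjustment within the comparison. Probe sets with adjusted p under 0.05 were called, with no fold threshold. The F-test covered the 3 genotype means. The fit was tested on simulated data with known changes for the triple mutant against wild type: over 5 simulations of 22746 probe sets, 38.8% of changes of 0.5 and 85.4% of changes of 1 on the log2 scale were recovered, and 5.62% of calls were false. The simulated noise was independent between arrays and had the same spread in all 3 genotypes. The rates may differ for the real arrays, where wild type was more spread and same-numbered arrays were correlated.

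Same-numbered arrays were checked for pairing by correlating their deviations from the genotype means across probe sets, before blocked calls were looked at. Between the triple mutant and wild type the 3 correlations were 0.273, 0.330 and 0.408, and between the 2 mutants they were 0.217, 0.340 and 0.515, so the numbers were read as pairing these arrays. The pairing comes from the titles' numbers and this check, not from a protocol. The blocked value stands beside a result of these comparisons where it changes a call or moves a count by over 1.5 times.

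The named genes were set by a rule written before the data were examined: PHV, IAA20 and IAA30 whatever their values (ARF5 and the other HD-ZIP III genes were in the rule and are not analysed here); the 10 highest and 10 lowest log2 changes among called probe sets with 1 gene whose 3 arrays in one genotype all lay on one side of the 3 in the other; and up to 4 called members of each gene list with the largest change. A gene with several probe sets was represented by the brightest one outside the second part. Members of the lists fixed before the data that did not pass over all probe sets are named where they passed over the list alone, and these were chosen after their values were seen; for the families only their count is given. In a list with 1 measured member such a p is not adjusted, so none is given. Gene lists were 18 sets fixed before the data were examined and 27 families defined from gene symbols after the annotation was read and before any fold change was computed. The 30 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 90 tests; 8 tests passed, 0 of them with an estimated correlation or with fry, which asks whether a list moves one way and not whether it differs from other genes. Overlaps were set against 100 simulations of unchanged groups with 1 spread for all arrays and, chosen after the data were seen, 100 with the mean spread of each genotype; neither models the pairing of replicate numbers.

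Alternatives were the replicate number as a block, a minimum mean log2 value of 5, quantile normalization, median centring, a variance trend with robust estimation, array weights, 1 probe set per locus, fits of the 6 arrays compared, a 2-fold minimum, fry, and leaving out each array in turn. Leaving out the 3 arrays numbered 3, like the second set of simulations, was added after the data were seen.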

Results

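Gene expression was measured in the terminal 0.5 mm of Arabidopsis thaliana primary roots, 4 days after germination, in 3 genotypes with 3 biological replicates each. Wild type was Col er-2. The triple mutant carried cna-2, phb-13 and phv-11, and the quadruple mutant carried rev-6 as well. The mutated genes encode HD-ZIP III transcription factors, a plant family known for its part in organ polarity and vascular patterning. Quadruple homozygotes were picked from a segregating population by their radial cotyledons, whereas no such sorting is described for the other genotypes. For the quadruple mutant the labels give the PHV allele in 2 ways, as phv-11 and as phv-6, and its titles write phb1 where its other labels give phb-13. Each of the 9 arrays gave a log2 signal for 22746 probe sets, and array medians lay between 5.79 and 5.95. The wild-type medians, at 5.79 to 5.89, all lay below the mutant medians, at 5.91 to 5.95. The number of arrays limits the precision of every value. Correlations between replicate arrays, taken across probe sets, were 0.990 to 0.994 in wild type, 0.994 to 0.997 in the triple mutant and 0.995 to 0.997 in the quadruple mutant, so the wild-type arrays were the most spread.

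PHV (AT1G30490) was the 1 gene of the 5-member HD-ZIP III family with a listed probe set, and it was low in both mutants. Its log2 signal was 7.23 ± 0.08 (SD, n = 3) in wild type, 4.75 ± 0.03 (SD, n = 3) in the triple mutant and 5.15 ± 0.10 (SD, n = 3) in the quadruple mutant. This was a 5.58-fold lower level in the triple mutant, with a log2 change of -2.48 (SE 0.09, limma adjusted p = 8.49e-07), and a 4.22-fold lower level in the quadruple mutant, with a log2 change of -2.08 (SE 0.09, limma adjusted p = 5.70e-06). PHV was 0.40 higher on the log2 scale in the quadruple than in the triple mutant (SE 0.09, limma adjusted p = 0.0405), a call that held without wild-type replicate 2 or 3 and ended in the other 7 of the 9 fits that left out 1 array, with adjusted p up to 0.170. PHV is mutated in both mutants, so its level does not check which of them carries rev-6. REV, PHB, CNA and ATHB8 were not analysed here, because no listed probe set names them.

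**Figure D1:**
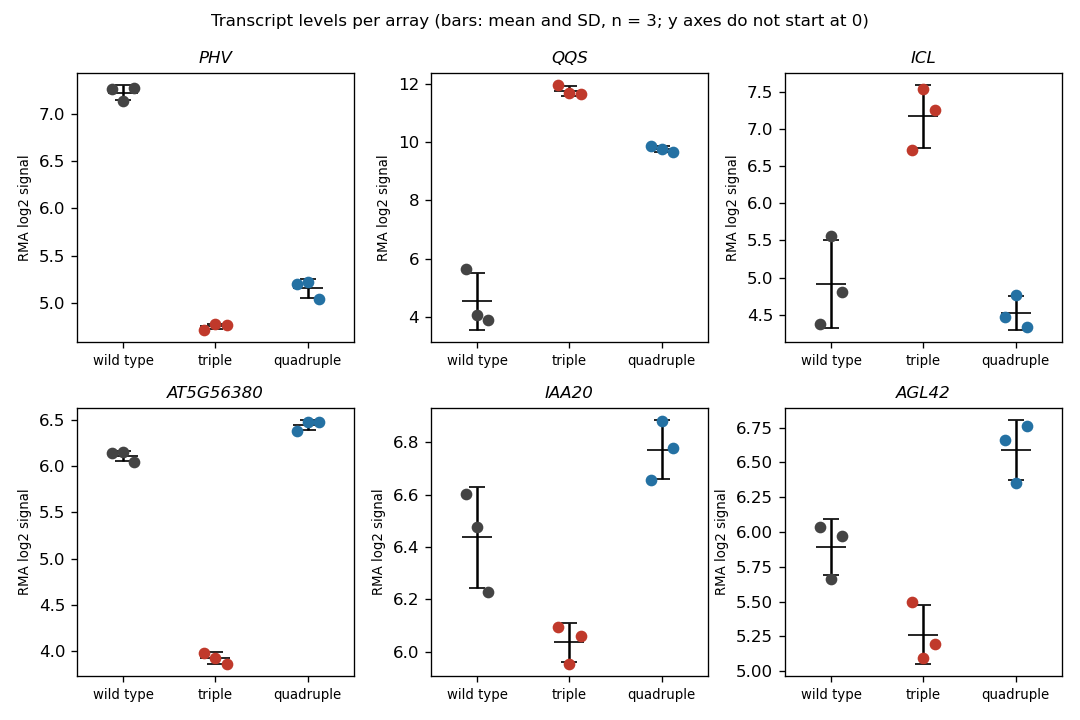
RMA log2 signal of 6 genes on each of the 9 arrays, with 1 panel per gene, the genotype on the horizontal axis and the log2 signal on the vertical axis; points are arrays and bars are the mean and SD of 3 arrays. PHV is low in both mutants, QQS is high in both, and ICL and AT5G56380 differ in the triple mutant from the other 2 genotypes.

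The first comparison asked what the mutations in CNA, PHB and PHV change in the root tip. QQS (AT3G30720), an orphan gene known for its effect on starch content, had a log2 signal of 4.54 ± 0.96 (SD, n = 3) in wild type, 11.76 ± 0.16 (SD, n = 3) in the triple mutant and 9.76 ± 0.11 (SD, n = 3) in the quadruple mutant. It rose in the triple mutant, with a log2 change of 7.22 (SE 0.36, limma adjusted p = 1.38e-05), whose exact size depends on wild-type signals of 3.90 to 5.65, under the array medians, with no detection call used here. ICL (AT3G21720), which encodes the glyoxylate cycle enzyme isocitrate lyase, rose by 2.26 on the log2 scale (SE 0.29, limma adjusted p = 0.00398). XTH18 (AT4G30280), a xyloglucan endotransglucosylase, was 3.28-fold higher (log2 change 1.71, SE 0.16, limma adjusted p = 0.00122). CLE41 (AT3G24770), the precursor of a peptide that regulates vascular stem cells, was 2.43-fold higher (log2 change 1.28, SE 0.19, limma adjusted p = 0.00763). The other strongest named rises were AT4G09760, AT2G27830, AT4G16563, AT4G30170, AT5G12050, AT1G72900, AT5G42250 and AT2G18690, with log2 changes from 1.73 to 2.31. After PHV, the strongest named falls were AT5G56380 (log2 change -2.18, SE 0.08, limma adjusted p = 8.49e-07), AT5G55790 (-1.56), AT4G39970 (-1.28), AT5G22580 (-1.21) and CYP51G2 (-1.11), a cytochrome P450. AT1G47410, AT1G74770, AT4G39955 and the glutathione S-transferase gene ATGSTF13 fell by 0.86 to 1.00 on the log2 scale.

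Of 47 UDP-glycosyltransferase genes measured, which attach sugars to small molecules, 7 rose and 0 fell in the triple mutant, and 12 were higher when adjusted over the list alone. The largest of these changes were in UGT73B1 (log2 change 1.23), UGT73C7 (1.19), UGT76B1 (1.15) and UGT73B5 (0.93). The family ranked above other genes in the set test (camera adjusted p = 0.0111), but not with an estimated correlation between genes (adjusted p = 0.715 with an estimated correlation). Its mean log2 change was 0.16 and its median 0.03, against a median of -0.02 over all probe sets; after quantile normalization the list's median was 0.06, and after median centring, which moves all probe sets alike, its mean was 0.06 and its median -0.07, against -0.12 over all probe sets. None of the set tests given here as passing with camera passed with fry, where adjusted p was 0.118 or above. Without triple-mutant replicate 2 the camera adjusted p was 0.112. Among 13 genes of cold, drought and late embryogenesis responses, the dehydrin LTI30 rose by 1.06 and the other 12 did not pass the threshold, although 5 of the 13 were higher when adjusted over the list alone; the set test gave a camera adjusted p = 0.00482, and an adjusted p = 0.685 with an estimated correlation. Without triple-mutant replicate 2 the camera adjusted p was 0.0933. The auxin glucosyltransferase gene IAGLU rose by 0.57. The tetraspanins TET8 and TET6 rose by 0.77 and 0.62, and the U-box ubiquitin ligases PUB22 and PUB23, known from immune signalling, rose by 1.00 and 0.78. SWEET2, a sugar transporter gene, rose by 0.91, whereas the log2 changes of the other 13 of 14 SWEET genes measured were negative and did not pass, although 3 of them were lower when adjusted over the list alone; 3 of the 14 were positive after quantile normalization. The family ranked low as a set (camera adjusted p = 0.0314, adjusted p = 0.685 with an estimated correlation), but not after quantile normalization (0.154) or without wild-type replicate 2 (0.144), triple-mutant replicate 1 (0.0738) or triple-mutant replicate 3 (0.0622). XTH19 (0.79), CYP71B26 (1.23), ATPC1 (0.88) and UGT76C1 (0.48) rose and TRM23 (-0.47) fell. Of the 38 named genes that passed in this comparison, 23 passed in each of the 9 fits without 1 array and 15 did not. ATPC1, LTI30, PUB22, PUB23, TRM23, UGT73B5, UGT76C1 and XTH19 lost their call in 5 or more of them. UGT73B5, ATPC1 and UGT76C1 also lost it after either quantile normalization or median centring, TRM23 after the former, and XTH19 and LTI30 after the latter.

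The lists fixed before the data were examined were thinly covered, with 31 of 296 genes having a listed probe set, and none but the HD-ZIP III list held a gene past the threshold in the triple mutant. IAA20, an Aux/IAA repressor, stood at a log2 change of -0.40 (SE 0.11, limma adjusted p = 0.124) and IAA30 at -0.07 (SE 0.15, limma adjusted p = 0.882). Without wild-type replicate 3 IAA20 passed, at -0.50 (adjusted p = 0.0479). Adjusted over the list alone, 1 of the 7 measured Aux/IAA genes, IAA20, was lower (adjusted p = 0.0323). The quiescent-centre gene AGL42 stood at -0.63 (limma adjusted p = 0.0737) and the stress regulator STZ, which is the 1 measured member of 17 wounding and handling genes, at 1.14 (limma adjusted p = 0.149). Both passed with the replicate number as a block, at adjusted p = 0.00516 and 0.00779, and AGL42, of 2 measured members, passed when adjusted over the list alone (adjusted p = 0.00352). Over the list alone, but not with the block, so did the phloem gene OPS, also of 2 measured members (log2 change 0.53, adjusted p = 0.00547).

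Across all probe sets, 393 of 22746 passed the threshold between the triple mutant and wild type, 337 higher and 56 lower (limma, adjusted p under 0.05). With the replicate number as a block the count was 1152, of which 941 were higher and 211 lower. The split between higher and lower depended on the scaling, with 214 higher and 102 lower after median centring. Without wild-type replicate 1 the count was 647. It was 194 without wild-type replicate 2, 182, 199 and 254 without triple-mutant replicates 1, 2 and 3, and 249 without quadruple-mutant replicate 1. Of the 393 probe sets, 182 had no listed gene and so could not be named. On the 3 triple-mutant arrays the hybridization spike-in controls lay at 10.16 or above on the log2 scale, and on the other 6 arrays at 10.07 or below.

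The second comparison asked what the mutations in all 4 genes change. The named genes that passed in the quadruple mutant against wild type were 3: PHV, QQS and AT2G32560. QQS had a log2 change of 5.22 (SE 0.36, limma adjusted p = 3.35e-04), against the same low wild-type signals. AT2G32560 was 1.63-fold higher, with a log2 change of 0.70 (SE 0.08, limma adjusted p = 0.0218), but it did not pass after median centring (adjusted p = 0.0652) or in 6 of the 9 fits without 1 array (adjusted p up to 0.168). These values are from 1 of the gene's 2 listed probe sets, and the other did not pass. IAA20 stood at a log2 change of 0.34 (SE 0.11, limma adjusted p = 0.459) and IAA30 at 0.08 (SE 0.15, limma adjusted p = 0.892), the latter turning to -0.0093 after quantile normalization and -0.011 after median centring. Some list members passed when adjusted over the list alone: both measured genes of the quiescent-centre and stem-cell list, AGL42 (log2 change 0.70) and BBM (0.60), the type-A cytokinin response regulator ARR15 (0.96) and the root-hair expansin EXPA7 (-0.21), the last 2 each of 2 measured members. None of these passed over all probe sets, where adjusted p was 0.203, 0.0947, 0.168 and 0.501.

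In all, 10 probe sets passed between the quadruple mutant and wild type, 5 higher and 5 lower, and 2136 had an unadjusted p under 0.05. Without wild-type replicate 1 the count was 59, and with each of the other arrays left out in turn it lay between 4 and 13. As a set, 69 plastid-encoded genes ranked high in both mutants against wild type, with a median log2 change of 0.16 in the triple mutant (camera adjusted p = 0.00305, adjusted p = 0.748 with an estimated correlation) and 0.17 in the quadruple mutant (camera adjusted p = 0.00170, adjusted p = 0.748 with an estimated correlation). The medians were 0.10 and 0.11 after quantile normalization, and 0.06 and 0.08 after median centring, which moves all probe sets alike. No single plastid gene passed, and without wild-type replicate 3 the camera adjusted p was 0.596 and 0.585. It was 0.354 in the quadruple mutant without its replicate 3, and 0.0787 in both mutants over probe sets with a mean log2 value of at least 5.

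The third comparison asked what the added rev-6 allele changes in the triple-mutant background. Most of the strongest changes ran opposite to those of the triple mutant against wild type. Both comparisons hold the same triple-mutant arrays, so part of this opposition is built in. Across probe sets the log2 changes of these 2 comparisons correlated at -0.72. Simulations of unchanged groups with 1 spread for all arrays gave -0.50. AT4G30170 was 8.13-fold lower in the quadruple than in the triple mutant (log2 change -3.02, SE 0.34, limma adjusted p = 0.00146), ICL was 6.25-fold lower (-2.64, SE 0.29, limma adjusted p = 0.00126), XTH18 was 3.71-fold lower (-1.89, SE 0.16, limma adjusted p = 3.85e-04) and CLE41 was 2.92-fold lower (-1.54, SE 0.19, limma adjusted p = 0.00201). AT5G56380 was 5.71-fold higher (log2 change 2.51, SE 0.08, limma adjusted p = 4.11e-07). AGL42, expressed in the quiescent centre, was 2.52-fold higher (1.33, SE 0.15, limma adjusted p = 0.00149), and BBM, a stem-cell AP2 factor, rose by 0.45 (limma adjusted p = 0.0353), so both measured genes of the 9 on that list rose. BBM lost its call in 5 of the 9 fits without 1 array.

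Of 23 genes on a wider auxin list, 2 were higher, 2 were lower and 19 did not pass (camera adjusted p = 0.900). IAA20 was 1.67-fold higher in the quadruple mutant (log2 change 0.74, SE 0.11, limma adjusted p = 0.00759) and was the 1 measured Aux/IAA gene of 7 to pass; 2 of the 7, with IAA33, passed when adjusted over the list alone. The auxin-conjugating enzyme gene WES1, also called GH3.5, rose by 0.70 (limma adjusted p = 0.0243), while the auxin glucosyltransferase genes UGT74D1 (-0.70) and IAGLU (-0.42) fell, calls lost in 7 and in 9 of the 9 fits without 1 array. IAA30 stood at 0.15 (limma adjusted p = 0.882). IAA33 stood at 0.71 and ARR15 at 0.67, with adjusted p = 0.154 and 0.115; with the replicate block these were 0.0390 and 0.0167. The phloem gene OPS stood at -0.61 with adjusted p = 0.05002, just over the threshold, and 0.0375 with the replicate block. STZ stood at -1.16, with adjusted p = 0.147 and 0.00663 with the replicate block. OPS, ARR15 and the auxin-conjugating enzyme gene GH3.1 (-0.33, limma adjusted p = 0.247) passed when adjusted over the list alone.

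The UDP-glycosyltransferases ranked low as a set (camera adjusted p = 9.90e-04, adjusted p = 0.685 with an estimated correlation), with 7 of 47 lower and 0 higher, or 9 lower when adjusted over the list alone, among them UGT73B1 (-1.37), UGT76B1 (-1.35), UGT73C7 (-1.10) and UGT71C1 (-0.85). The cold, drought and late embryogenesis genes ranked low too (camera adjusted p = 0.00482, adjusted p = 0.685 with an estimated correlation), with LTI30 at -1.49 as the 1 gene past the threshold; without triple-mutant replicate 2 the camera adjusted p was 0.0933. The other strongest named rises were AT1G23160, AT5G22580, AT3G48460, AT1G29270, AT5G55790, AT1G47410, ATGSTF13 and AT5G64710, with log2 changes from 1.20 to 2.03. The other strongest named falls were AT4G09760, AT2G45180, AT1G72900, AT1G76470, AT2G25450, AT1G05575, QQS and AT2G27830, with log2 changes from -2.47 to -1.96. CYP51G2 (1.18), BGLU44 (1.02), TBL45 (0.63), GH9B8 (0.62) and SWEET17 (0.60) also rose, and CYP71B26 (-0.95), PUB23 (-0.92), ATPC1 (-0.86), TBL37 (-0.82), scpl18 (-0.76), TET8 (-0.72), EXPB1 (-0.72) and TET6 (-0.57) fell. Of the 46 named genes that passed in this comparison, 25 passed in each of the 9 fits without 1 array and 21 did not. AT1G05575, ATPC1, BBM, BGLU44, CYP71B26, EXPB1, GH9B8, PHV, IAGLU, QQS, SWEET17, TBL37, TET6, UGT71C1, UGT74D1 and WES1 lost their call in 5 or more of them. BGLU44, EXPB1 and TBL37 also lost it after quantile normalization, and IAGLU after median centring.

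Across all probe sets, 504 passed between the quadruple and the triple mutant, 126 higher and 378 lower. With the replicate block the count was 1114, with 296 higher and 818 lower, and with array weights it was 1663, with 640 higher and 1023 lower. It was 220 and 298 without triple-mutant replicates 1 and 2, and 235, 238 and 295 without quadruple-mutant replicates 1, 2 and 3. Of the 504 probe sets, 231 had no listed gene. Here too the hybridization spike-in controls were higher on the triple-mutant arrays.

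**Figure D2:**
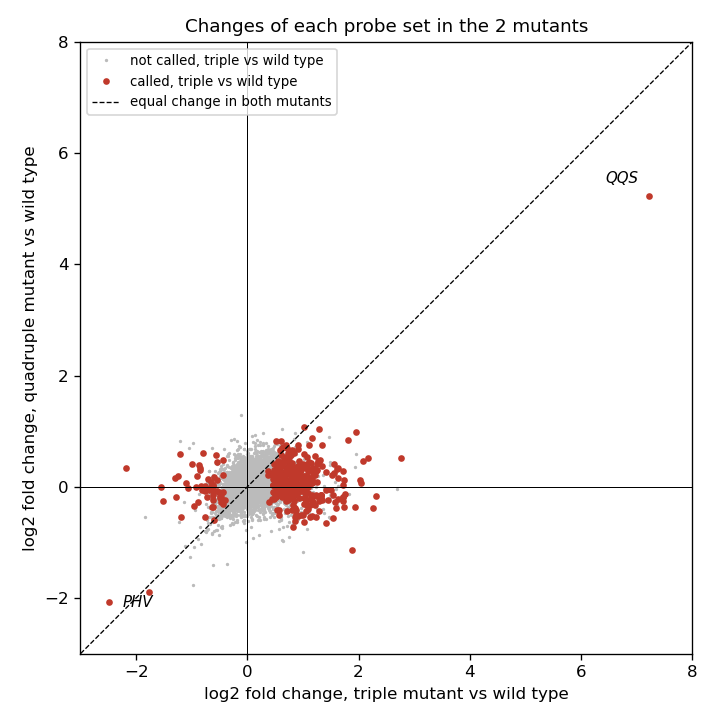
Log2 fold change of each of the 22746 probe sets in the triple mutant (horizontal axis) and in the quadruple mutant (vertical axis), each against the same 3 wild-type arrays; red points passed the threshold between the triple mutant and wild type, and the dashed line marks equal change. Most of the 393 red points lie near 0 on the vertical axis, whereas QQS and PHV lie far from 0 on both.

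The changes of the triple mutant were mostly not carried into the quadruple mutant. Over the 337 probe sets higher in the triple mutant the median log2 change was 0.84 in the triple and 0.10 in the quadruple mutant, and over the 56 lower ones it was -0.72 and -0.04. Of the 393 probe sets, 248 passed in the opposite direction between the quadruple and the triple mutant. Independent lists would share 5.91, and unchanged groups sharing the triple-mutant arrays gave at most 1 in 100 simulations. The call lists of the 2 mutants against wild type shared 6 probe sets in the same direction, against 0.0864 for independent lists. Unchanged groups sharing the wild-type arrays gave 0 in 100 simulations, and at most 1 when each genotype kept its own spread. None of these figures says how many probe sets lists of these lengths would share through the shared arrays. Unchanged groups hold no changed probe set, so few can pass in them, and independent lists share no arrays. The 6 became 44 without wild-type replicate 1, and 3 after median centring and in 6 of the other 8 fits without 1 array. The covariance of the log2 changes of the 2 mutants was 0.0195. Simulations of the shared wild-type arrays alone gave 0.00933 with 1 spread for all arrays and 0.0164 with the wider spread of wild type. Because the wild-type arrays were the most spread, the 0.0164 is closer to these data than the 0.00933. The former would be most of the covariance and the latter would not. Neither models the pairing of replicate numbers, so the part due to the shared arrays is not settled. With 3 wild-type arrays the controls could not be split into 2 sets of at least 2 arrays. Over all 3 genotypes, 474 probe sets passed the F-test, 1325 with the replicate block and 1243 with array weights, and between 201 and 315 without triple-mutant replicate 1 or 2 or any 1 quadruple-mutant array.

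Marker genes of cell types told little, because few had a listed probe set. Over all probe sets and without the replicate block, no gene passed in limma in any comparison among the 1 measured of 28 xylem vessel genes, 1 of 8 xylem precursor genes, 2 of 23 phloem genes, 1 of 14 endodermis genes, 2 of 15 epidermis genes, 2 of 28 cell cycle genes, 2 of 10 type-A response regulators, 1 of 16 gibberellin and brassinosteroid genes or 3 of 20 polarity genes. Of the 3 fixed lists with enough measured members for the set test (Aux/IAA, auxin synthesis and transport, and polarity genes), 0 passed with camera in any comparison. The nearest was Aux/IAA between the 2 mutants (camera adjusted p = 0.0762, adjusted p = 0.685 with an estimated correlation), which did pass with fry (adjusted p = 0.0299). The lists of auxin response factors, cytokinin metabolism, root cap and shoot genes had 0 measured members. RNA quality, read as the log2 difference between 3-prime and 5-prime probe sets averaged over actin, GAPDH and ubiquitin, was 1.25 ± 0.34 (SD, n = 3) in wild type, 1.20 ± 0.17 (SD, n = 3) in the triple mutant and 1.39 ± 0.45 (SD, n = 3) in the quadruple mutant. Two-sided exact permutation tests gave p = 0.8 for each mutant against wild type and p = 0.7 between the mutants, where 3 arrays against 3 allow no p under 0.1.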

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

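The tests on RNA quality, the exchange of labels, QQS, the spike-in controls, the time of harvest and the 36 groupings by replicate number were chosen after their results or the main ones were seen; those on the other groupings of the arrays were set before. The poly-A spike-in controls, bacterial transcripts added to the RNA and used in no comparison, lay above every wild-type array on 2 mutant arrays: their mean log2 signal was 7.20 on triple-mutant replicate 3 and 6.71 on quadruple-mutant replicate 3, against 4.82, 4.95 and 5.25 in wild type. The hybridization spike-in controls, also outside the comparisons, lay above every wild-type array on the 3 triple-mutant arrays, at 10.17, 10.16 and 10.29, against 9.83 to 10.07 in wild type. The 25S and 5S ribosomal RNA controls lay at 6.87 and 6.49 on quadruple-mutant replicates 1 and 2 and at 8.18 on replicate 3. They lay at 7.33 to 8.28 in wild type and 7.95 to 8.21 in the triple mutant, and no test was run on them.

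The spike-in signals could mark arrays that drive the calls. The tables argue against the arrays numbered 3 as the only source of the calls between the triple mutant and wild type: with only the arrays numbered 1 and 2, 166 probe sets passed there, 2 between the quadruple mutant and wild type and 377 between the mutants. A part played by the arrays numbered 3 in the other calls was not tested. A hybridization difference of the triple-mutant arrays stays open. Their hybridization controls exceeded those of wild type by 0.22 on the log2 scale, less than the 0.63 that marks the lower quartile of called changes, but all 3 arrays of that genotype carry it, so it cannot be told apart from the genotype.

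The triple mutant stood apart from the other 2 genotypes: 393 and 504 probe sets separated it from wild type and from the quadruple mutant. Wild type and the quadruple mutant differed by 10, or by 59 without wild-type replicate 1. Such counts are not distances. The mean squared log2 difference beyond the noise between arrays was 0.0402 and 0.0352 for the triple mutant against wild type and the quadruple mutant. It was 0.0113 between those 2. The triple mutant stood apart by this measure too, but by less than the counts show. As the cause, RNA quality stays open: the 3-prime minus 5-prime difference averaged 1.20 in the triple mutant, with its arrays at 1.02 to 1.36 within the 0.86 to 1.88 of the other 6, but against wild type actin stood at -0.30 and ubiquitin at 0.24, and on replicate 3 actin lay below and ubiquitin above all 6. A different time of harvest stays open, as of the 2 evening-phased genes measured GI stood at 0.20 and COR27 at 0.72 (limma adjusted p = 0.480 and 0.169, and 0.286 and 0.0341 with the replicate block), which are too few to decide. An exchange of the triple and quadruple labels cannot be told apart from the labels as given, since REV is not analysed here and PHV, which was 0.40 higher in the quadruple mutant, is mutated in both. An effect of rev-6 on the triple-mutant changes, and the sorting of quadruple seedlings by cotyledon shape, stay open as biological explanations and were not tested.

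QQS was high on all 6 mutant arrays, and a level that follows the number of mutated HD-ZIP III genes stays open. As labelled, QQS was lower in the quadruple than in the triple mutant, with a log2 difference of -2.00 (SE 0.36, limma adjusted p = 0.0204, 0.00225 with the replicate block), which goes against it, but an exchange of the 2 labels would turn the sign. Without 1 array the difference stayed between -2.06 and -1.90, while 6 of the 9 fits put the adjusted p over the threshold, at up to 0.0921. These p-values rest on a spread shared by all 3 genotypes, which for QQS comes mostly from wild type. Its SD was 0.96, against 0.16 in the triple and 0.11 in the quadruple mutant. The arrays of the 2 mutants lay at 11.65 to 11.95 and at 9.65 to 9.88. A stable state of the QQS locus carried by each line, whatever the mutated genes do, may be the source. It cannot be told apart from an effect of the mutations, because the labels name 1 line per genotype: within a genotype QQS ranged over at most 1.75, in wild type, and the smallest gap between genotypes was 1.78.

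Chance is an unlikely source of the F-test calls. Of 100 groupings of the 9 arrays drawn from 280, only 1, the real one, gave as many as 474 probe sets. So did 1 of the 36 groupings with each replicate number once per group, again the real one, where the highest of the others gave 237, or 689 against 1325 with the replicate block. Among the 100, the highest of the others gave 332 and kept the 3 triple-mutant arrays together while mixing wild type with the quadruple mutant, which points to a structure set by the triple mutant. Grouping by replicate number, fitted apart from the 100, gave 31. For the comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05. The real splits gave 393, 10 and 504 probe sets and the highest of the others 0 in each comparison, both for the 3 others that part all same-numbered pairs and for the 6 that part 1 pair.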

How the results depend on the processing

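Leaving out the arrays numbered 3 was chosen after the data were seen; the other settings were planned. Of the 8 set tests that passed, 0 did with an estimated correlation and 0 with fry. Some families that did not pass with camera did pass with fry in triple mutant against wild type. These were the tetraspanins, the xyloglucan endotransglucosylases, and the cytokinin response regulators and glucosylation genes (fry adjusted p = 0.0277 each). With the replicate block, 1152 probe sets passed between triple mutant and wild type, 67 between quadruple mutant and wild type, 1114 between the mutants, 1325 in the F-test and 27 in the overlap of the 2 lists. For quadruple mutant and wild type the same-numbered correlations were 0.0427, 0.342 and 0.360. Because 1 of them is low, the numbers were not read as pairs there. Yet each of the 9 arrays correlated best with its own number when the correlations were averaged over the other 2 genotypes. Between quadruple mutant and wild type alone this did not hold for wild-type replicate 1. It stood at 0.0453 with quadruple-mutant replicate 2 and at 0.0427 with replicate 1. The pairs read in the other 2 comparisons would link the arrays of quadruple mutant and wild type too. The pairing of these 2 genotypes is thus not settled. With the block, 50 of their 67 probe sets were higher and 17 lower, and AGL42, BBM and ARR15 passed at limma adjusted p = 0.0251, 0.0325 and 0.0251. Apart from AGL42, STZ, OPS, IAA33, ARR15 and COR27 in the paired comparisons, the block changed no call printed in the text for those comparisons. With 1 probe set per locus, which tests 13333, the counts were 192, 3, 257 and 234 in the F-test. With the 6 arrays compared they were 167 and 5 against wild type, with fewer arrays behind the spread. With a 2-fold minimum they were 135, 5 and 164. Array weights gave 1663 between the mutants and 1243 in the F-test, and median centring an overlap of 3; the cause was not tested. Without the arrays numbered 3, the counts were 166, 2 and, in the F-test, 215, from fewer arrays.

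Leaving out 1 array gave 182 to 647 between triple mutant and wild type, 4 to 59 between quadruple mutant and wild type, 220 to 610 between the mutants, 201 to 654 in the F-test and 3 to 44 in the overlap. The highest values against wild type, in the F-test and in the overlap came without wild-type replicate 1. PHV lay between 0.37 and 0.46 in quadruple against triple mutant. IAA30, never called, changed sign: in quadruple mutant against wild type it was -0.0093 after quantile normalization and -0.011 after median centring, and lay between -0.051 and 0.27 without 1 array. In triple mutant against wild type IAA30 lay between -0.20 and 0.12 without 1 array. Median centring moved the median of all probe sets to -0.12 in triple mutant against wild type, and gave 2 higher and 5 lower in quadruple mutant against wild type. Of the other named genes, 7 lost their call after quantile normalization and 7 after median centring, and none with the block. The filter on dim probe sets removed 11 named genes, so they were not tested there, and ended no call among the rest. Array signals near the floor limit the sizes of low genes.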

Other observations

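Tests of gene order among the falls were chosen after their genes were seen; the test around the mutated genes was set before.

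Some genes that fell in the triple mutant, and did not pass in the quadruple mutant against wild type, are neighbours. AT5G56370 and AT5G56380, on chromosome 5, stood at -0.76 and -2.18 in the triple mutant against wild type and at -0.08 and 0.33 in the quadruple mutant. AT4G39955 and AT4G39970, on chromosome 4, stood at -0.91 and -1.28 in the triple and at 0.19 and -0.19 in the quadruple mutant. Linked variants or an altered segment in the triple-mutant line may lie behind such pairs. Over all 33 named falls on the 5 nuclear chromosomes, 4 had another fall among the 10 nearest measured genes on each side, where 10000 random gene sets gave a median of 2 and a 95th percentile of 4, so the number does not exceed chance (one-sided permutation p = 0.180).

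Passenger variants linked to the mutated genes would place calls around CNA, PHB and PHV. The test went against this as a common source close to the 3 loci: with PHV left out, 1 of 198 called genes lay among the 50 nearest measured genes on each side of the 3 loci, where random sets gave a median of 4 (one-sided permutation p = 0.990). Linked variants further from the loci, and probe sets without a listed gene, were not covered by the test.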
